A study of Mus musculus with 34 samples.

How the data were processed

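The series holds RNA from tracheal brushings of 28 Gprc5a knockout mice (baseline n = 6, t0 n = 6, t2 n = 5, t4 n = 6, t6 n = 5) and of 6 wild-type mice before exposure. Per the labels, RNA with an integrity number of at least 7 was used to make poly-A libraries read on an Ion Proton. Each library came from a separate mouse, per the series design.

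The deposited knockout table is named for RPKM, but its values are estimated counts: 76.3% of the values above 0 were whole within 0.01, and the libraries had different totals. Per the submitters' processing notes, mm10, STAR 2.4.1d, Bowtie2 2.1.0 and Partek were used, with roles and the Partek version not given in the sources used here. How the authors filtered genes, used strand or shared reads between genes is not given, so near-identical genes were treated as uncertain. The table had 24223 rows with symbols and mm10 coordinates, 27 symbols turned into dates and 4 rows with a repeated symbol, which were kept as separate genes. The wild-type files hold RSEM estimated counts, TPM and FPKM per the file headers, made with STAR 2.7.0f, RSEM 1.3.1 and GRCm38 per the submitters' processing notes. A symbol was found for 55094 of 55573 wild-type gene IDs (99.1%). Both sources were processed separately by the authors, so no test was run between genotypes.

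Estimated counts were rounded to whole numbers. Genes with at least 1 CPM in at least 5 libraries were kept (14847), and counts were scaled by TMM. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), robust, with a mean per group over all 28 libraries, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. A limma fit of log2(RPKM + 1) had been planned before the data were examined, and was replaced because the table holds counts. Limma 3.58.1 on log2 CPM with pseudocounts 1 and 0.1, and DESeq2 1.42.0, were run as alternatives. Comparisons were t0, t2, t4 and t6 against baseline, t2 and t6 against t0, an F test over the 5 groups and a linear trend over the 22 exposed libraries. CPM values in the text are TMM-scaled means ± SD, except those of Gprc5a and of the wild-type libraries, which are scaled by library totals. Effects that passed at 1 time only were not taken to differ between times unless tested.

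A set of 46 gene lists for cell types and pathways, chosen with the rest of the design, was tested with camera (preset correlation 0.01), adjusted over lists within a comparison. Estimated correlations and fry, which tests whether a list's genes move 1 way, stood beside it. Named genes were chosen by a rule: the largest rises and falls per comparison, the smallest p-values of the F test, the largest changes of each class over time, and the genes with the smallest p of each list that passed or had at least 3 called members, with the first of each ranking kept where length required it. Some genes that met the rule are not reported here. Among genes called at t0, those called at t6 in the same direction, and those that moved back by t6, were counted, as were genes called only late.

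On simulated counts for t0 against baseline (14847 genes), 13 of 67 genes changed 1.5-fold were found (19.4%), 43 of 67 changed 2-fold (64.2%) and 58 of 66 changed 4-fold (87.9%), with 5 false calls. The F test found 113 of 200 (56.5%), and the trend 161 of 200 (80.5%). A group with only 0 counts was set to a floor of 3 counts over the group. Ratios and floors cover counting error only, and reads without molecular identifiers are not independent molecules. Sex was read from Xist and Y-linked genes. Alternatives were other filters and scalings, quality weights, sex as a covariate, only the groups compared, each library left out in turn and the 4 doubted libraries left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.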

Results

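Airway epithelium was brushed from the trachea of Gprc5a knockout mice, animals lacking an epithelial receptor gene whose loss favours lung tumours, and its RNA was sequenced. Mice received the tobacco nitrosamine NNK at 50 mg/kg 3 times a week for 8 weeks, and 28 mice gave 1 library each. The groups were baseline before exposure (n = 6), t0 at the end of exposure (n = 6), and 2 (t2, n = 5), 4 (t4, n = 6) and 6 months later (t6, n = 5), when lung adenocarcinomas develop. Another 6 libraries came from unexposed wild-type mice. Total counts per knockout library ranged from 15.6 M to 37.6 M (baseline 22.7 to 29.7, t0 18.6 to 30.3, t2 21.2 to 29.5, t4 15.6 to 30, t6 24.3 to 37.6), and from 10.8 M to 24.0 M in the wild-type libraries. Libraries are named by group and animal number. Unexposed mice of the later ages were not analysed here, so age and time after exposure changed together in every comparison.

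Gprc5a (chromosome 6, 135065662 to 135084708, mm10) was low in the knockout libraries: counts were 17 to 41 at baseline, 6 to 23 at t0, 11 to 36 in 4 of the 5 t2 libraries, 6 to 45 at t4 and 4 to 49 at t6. The library labelled t2 339 held 238 counts (8.06 CPM), against at most 2.88 CPM in the other 27. Group means were 1.05 ± 0.317 CPM (SD) at baseline, 0.585 ± 0.347 at t0, 2.42 ± 3.17 at t2, 1.15 ± 0.912 at t4 and 0.805 ± 0.49 at t6. In the wild-type tables the estimated counts were 2115 to 8186, or 120 ± 54.8 TPM and 113 ± 41.8 FPKM (SD, n = 6). Both kinds of table were made separately, so no test was run. For the club-cell secretoglobin Scgb1a1, CPM was 34400 ± 17300 in wild-type and 32300 ± 6970 in knockout baseline libraries.

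**Figure D1:**
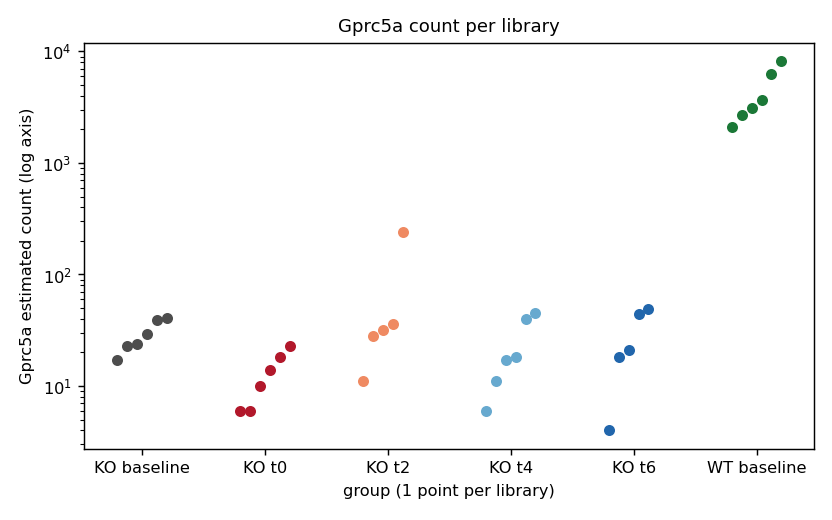
Gprc5a estimated count on a log axis for each library, by group. The library t2 339 lies at 238 counts, above the other 27 knockout libraries, and the wild-type libraries lie at 2115 to 8186.

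On log2(CPM + 1) of the genes tested, principal component 1 held 35.1% of the variance and separated t0 from the other groups, with 359 nearest to them (30.4 against 72.8 to 91.6 in the other 5). Component 2 held 12.9% and was highest in t2 339, in which 14283 genes lay above 0, against 17234 to 18088 in the other t2 libraries. Haemoglobin transcripts took 22.8% of counts in t0 357, 25.5% in t4 371 and 15.3% in t6 349, and at most 3.06% in the other knockout libraries. The ribosomal RNA precursor Rn45s took 14.8% in t6 365. Counts of Xist and of Y-linked genes gave 2 males and 4 females at baseline, 3 and 3 at t0, 2 and 3 at t2, 3 and 3 at t4, and 2 and 3 at t6. The male t2 334 also held 492 Xist counts.

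**Figure D2:**
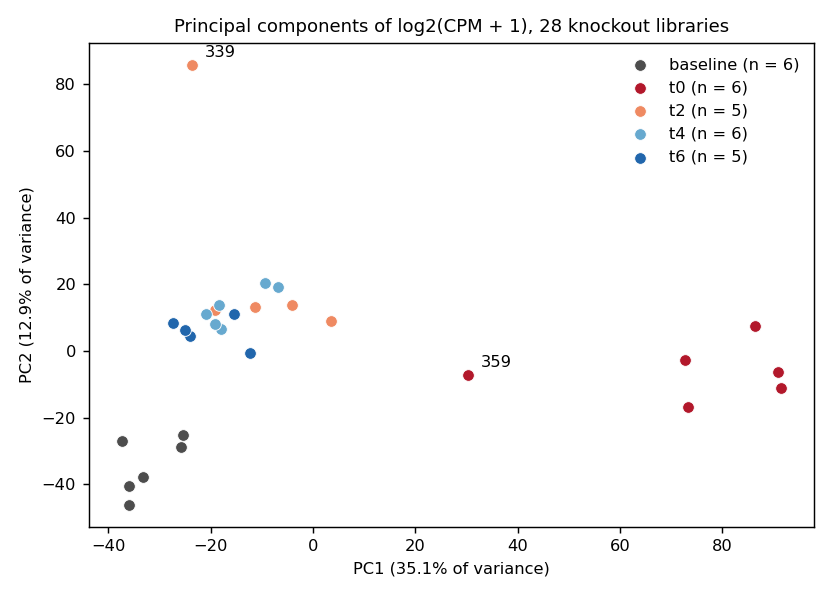
Principal components 1 and 2 of log2(CPM + 1) for the 28 knockout libraries, in units of the component scores, coloured by group, with 359 and 339 labelled. The t0 libraries lie to the right, from 30.4 (359) to 91.6 on component 1.

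The comparison of t0 with baseline addressed the early effect of the carcinogen. After 8 weeks of NNK, transcripts of secretory club cells were lower and those of p53 targets higher. Lists of ciliated cells (lower) and of squamous and basal epithelium and macrophages (higher) passed with the preset correlation between genes but not with an estimated one. Scgb1a1 (chromosome 19, 9083642 to 9087956), the main club-cell secretory protein, fell from 32300 ± 6970 CPM (SD, n = 6) to 701 ± 390 (n = 6), and the ciliary dynein Dnah5 from 694 ± 98.2 to 83.9 ± 86.9. In t0 359 Dnah5 was at 261 CPM, against 44.3 to 52.6 in the other 5, and its log2 value moved to −3.84 without it. The squamous keratin Krt4 rose from 129 ± 51.4 to 2620 ± 938 CPM, the cell-cycle inhibitor Cdkn1a from 64.6 ± 6.35 to 475 ± 181 and the macrophage marker Cd68 from 9.21 ± 1.67 to 162 ± 91.7. Of 14847 genes tested, 6761 changed (edgeR, adjusted p under 0.05): 3457 rose and 3304 fell, and 3185 changed at least 2-fold. Of 46 gene lists, 16 passed with the preset correlation and 2 with an estimated one. Scaled by library totals alone, 6240 changed and 69.4% of them rose, against 51.1% here, and the median of all genes moved from 0.02 to 0.19. With haemoglobin genes left out 49.8% rose. For 58 of the 81 called genes named, t0 and baseline libraries did not overlap. Lyz2, Polk, Rrm2b, Cyp3a13, Ces1d and Aldh3a1 had 5 of 6 t0 libraries on the called side of the baseline mean. Pvalb had 3 and Spt1 1. Named genes, here and below, were chosen by their changes, so such counts add no support.

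Parentheses after a gene give its log2 fold change ± SE and its adjusted p from edgeR, and list medians are log2 fold changes. Counts over the list alone were adjusted over its members only. The largest move of a log2 value by over 1 without 1 library is given, and other moves for some genes only. Atg9b (9.30 ± 0.73, 5.5e-10), an autophagy lipid scramblase, rose from 0.166 ± 0.119 to 108 ± 48.4 CPM, Nccrp1 (9.24 ± 0.96, 4e-08) from 0.0907 ± 0.0993 to 57.5 ± 41.9 and Cnfn (8.76 ± 1.35, 1e-05), a cornified-envelope protein, from 0.0647 ± 0.158 to 25.3 ± 18.9. All baseline counts of Cnfn lay in 352, without which it stood at 12.36 (3.7e-05). Fbxw27 (adjusted p = 3.6e-08) fell to 1 count over the t0 libraries from 464 at baseline, a ratio of 430 (95% exact interval 76.8 to 17000, counting error only), and its log2 value moved from −8.00 to −9.22 without t0 359. The cholecystokinin receptor Cckar (−5.68 ± 0.58, 3e-08), on chromosome 5, 53698485 to 53707704, fell from 174 ± 37.3 to 3.25 ± 4.13 CPM. Spt1 (12.36 ± 3.40, 0.0047) averaged 0.158 ± 0.271 and 861 ± 2110 CPM, but without t0 375 its value was −2.50 (adjusted p = 0.63). The muscle calcium buffer Pvalb (adjusted p = 0.0053) was at 0 in all baseline libraries and above 0 in 3 of 6 at t0. Its t0 mean was at least 225-fold higher (a bound of 104-fold without t0 367) than the floor (0.0192 CPM).

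Among genes of ciliated cells, 29 of 30 fell and 1 rose (29 and 1 over the list alone), median −2.04, adjusted p = 3.7e-20 (0.25 with an estimated correlation). Dnah5 (−3.05 ± 0.36, 2.2e-07) and the cilium transcription factor Rfx3 (−1.99 ± 0.24, 2.9e-07) led, while Mcidas (0.90 ± 0.27, 0.0071), which starts multiciliated differentiation, rose. Among genes of club cells, 13 of 14 fell and 1 rose (13 and 1 over the list alone), median −2.97, adjusted p = 1e-12 (0.032 with an estimated correlation). Scgb1a1 (−5.53 ± 0.41, 1.1e-10), Scgb3a1 (−4.56 ± 0.36, 2.9e-10), from 12100 ± 4540 to 513 ± 198 CPM, and the haptoglobin gene Hp (−3.97 ± 0.36, 3.6e-09) fell, and Gabrp (0.49 ± 0.15, 0.0079) rose. Of squamous epithelium genes, 9 of 15 rose (9 over the list alone), median 3.70, adjusted p = 6.2e-07 (0.23 with an estimated correlation). Krt4 (4.34 ± 0.32, 1.1e-10), the transglutaminase Tgm1 (3.70 ± 0.36, 1e-08) and Serpinb2 (6.97 ± 0.66, 1.2e-08) led. In the basal cell list, 12 of 18 rose (13 over the list alone), median 1.19, adjusted p = 1.2e-05 (0.25 with an estimated correlation). The basal keratins Krt14 (4.57 ± 0.50, 8.5e-08), from 6.33 ± 6.16 to 149 ± 47.7 CPM, and Krt5 (2.01 ± 0.28, 2.4e-06) and the hemidesmosome collagen Col17a1 (1.65 ± 0.22, 9.6e-07) rose. For neuroendocrine cell genes, 8 of 12 rose (8 over the list alone), median 1.22, adjusted p = 0.012 (0.73 with an estimated correlation). The granule protein Chga (1.33 ± 0.28, 0.00039) rose. For secreted antimicrobial proteins, 8 of 16 fell and 2 rose (9 and 2 over the list alone), median −1.38, adjusted p = 0.0024 (0.25 with an estimated correlation). The immunoglobulin transporter Pigr (−1.87 ± 0.18, 1.3e-08) and Bpifa1 (−3.34 ± 0.34, 2e-08) fell, whereas Defb1 (0.69 ± 0.16, 0.00093) and the protease inhibitor Slpi (2.98 ± 0.66, 0.00063) rose.

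Of p53 targets, 17 of 26 rose and 3 fell (18 and 3 over the list alone), median 0.86, adjusted p = 1.2e-05 (0.048 with an estimated correlation). Cdkn1a (2.88 ± 0.24, 6.6e-10), the stress sensor Sesn2 (1.54 ± 0.15, 7.8e-09) and Phlda3 (1.93 ± 0.19, 1.3e-08) rose, and Fas (−1.08 ± 0.27, 0.0019), Polk (−0.62 ± 0.18, 0.0077) and Rrm2b (−0.65 ± 0.16, 0.0016) fell. In the cell cycle list, 25 of 33 rose (26 over the list alone), median 1.29, adjusted p = 1.5e-05 (0.73 with an estimated correlation). The mitotic regulators Foxm1 (1.41 ± 0.22, 7.4e-06) and Cdc20 (1.76 ± 0.30, 2.8e-05) led. In the macrophage list, 17 of 19 rose and 1 fell (18 and 1 over the list alone), median 3.26, adjusted p = 9.2e-09 (0.25 with an estimated correlation), with Cd68 (4.14 ± 0.39, 6.4e-09) and the protease Ctss (4.10 ± 0.46, 1.4e-07) higher and the lysozyme Lyz2 (−0.76 ± 0.28, 0.03) lower. Among MHC class I genes, 12 of 17 rose (13 over the list alone), median 1.27, adjusted p = 1.2e-05 (0.5 with an estimated correlation). The peptide loading genes Tapbp (1.15 ± 0.13, 1.4e-07) and Tap2 (1.27 ± 0.18, 3.8e-06) led. Among MHC class II genes, 7 of 10 rose (8 over the list alone), median 1.73, adjusted p = 0.024 (0.86 with an estimated correlation). H2-Ab1 (2.18 ± 0.46, 0.00042) and Cd74 (2.32 ± 0.49, 0.00043) led. Of immune checkpoint genes, 8 of 10 rose (9 over the list alone), median 2.63, adjusted p = 0.0024 (0.25 with an estimated correlation), with Cd80 (2.87 ± 0.47, 1.7e-05) and Tigit (5.95 ± 1.00, 2.3e-05) first. For NF-kB and cytokine genes, 11 of 21 rose (11 over the list alone), median 0.95, adjusted p = 0.006 (0.77 with an estimated correlation). Nfkb2 (1.33 ± 0.23, 3e-05) and Il1a (3.83 ± 0.71, 8e-05) led. For T and NK cell genes, 11 of 18 rose (11 over the list alone), median 2.36, adjusted p = 0.04 (0.89 with an estimated correlation). Cd2 (4.33 ± 0.63, 3.4e-06) and Cd5 (3.61 ± 0.87, 0.0013) led. The call was lost without 1 library for Lyz2 (adjusted p up to 0.093 without baseline 343 or 352 or t0 332, 359, 367 or 374) and the T and NK list (up to 0.16 without baseline 343, 352 or 355 or t0 375).

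Of phase I xenobiotic enzymes, 13 of 26 fell and 4 rose (13 and 4 over the list alone), median −0.48, adjusted p = 0.03 (0.88 with an estimated correlation). Cyp4b1 (−1.67 ± 0.18, 4.5e-08) and the aldehyde oxidase Aox3 (−1.66 ± 0.19, 7.9e-08) fell, while Ces1g (2.05 ± 0.47, 0.00074), Cyp3a13 (0.86 ± 0.28, 0.014), Aldh3a1 (0.86 ± 0.24, 0.0041) and Ces1d (0.35 ± 0.14, 0.042) rose, with reads of the Ces1 genes hard to tell apart. In the skeletal muscle list, 13 of 15 rose and 1 fell (14 and 1 over the list alone), median 4.72, adjusted p = 0.03 (0.89 with an estimated correlation). The median here and at t2, t4 and t6 was the same with Pvalb at its bound. The troponins Tnni2 (4.32 ± 0.83, 0.00014) and Tnnc2 (6.95 ± 1.74, 0.0021) led, and the slow myosin Myh7 (−1.67 ± 0.56, 0.016) fell. Lists with at least 3 called members that did not pass were led by Lgr6 (−2.47 ± 0.25, 1.8e-08), Notch1 (1.66 ± 0.15, 4.8e-09), Atp6v1c2 (−2.78 ± 0.26, 7.1e-09) and Sftpa1 (−4.35 ± 0.40, 5.1e-09) for Wnt targets, Notch, ionocytes and alveolar epithelium. For STAT3 targets, hypoxia, circadian clock and interferon response these were Pim1 (1.95 ± 0.24, 2.9e-07), Bnip3 (−1.88 ± 0.23, 2.7e-07), Hlf (1.34 ± 0.16, 2.9e-07) and Mx1 (1.54 ± 0.20, 5.5e-07). For cholesterol synthesis, goblet cells, B cells and NRF2 targets they were Insig1 (−1.70 ± 0.19, 6.8e-08), Creb3l1 (−1.69 ± 0.22, 1e-06), Cd22 (6.15 ± 0.84, 1.8e-06) and Taldo1 (0.87 ± 0.12, 2.5e-06). DNA repair was led by the methylguanine repair enzyme Mgmt (1.45 ± 0.21, 3.3e-06), phase II enzymes by Ugt1a7c (3.51 ± 0.50, 2.6e-06), endothelium by Vwf (2.44 ± 0.35, 2.8e-06) and EGFR ligands by Ereg (6.11 ± 0.88, 3.8e-06). Respiratory chain, tuft, submucosal gland and mast cell lists were led by Cox7b (−0.86 ± 0.13, 4.8e-06), Rgs13 (−3.08 ± 0.47, 7.8e-06), Wfdc18 (3.35 ± 0.61, 8.6e-05) and Tpsb2 (−3.66 ± 0.71, 0.00013). Ribosomal, unfolded protein, heat shock and immediate early lists were led by Rps9 (0.70 ± 0.15, 0.00059), Asns (−0.82 ± 0.19, 0.0011), Hsp90aa1 (−1.12 ± 0.29, 0.0022) and Cyr61 (−2.45 ± 0.75, 0.01). Leaving out 1 library ended the calls of Ces1d (adjusted p up to 0.12 without baseline 344, 345 or 355 or t0 332, 367 or 374), Cyr61 (up to 0.052 without baseline 343), Myh7 (up to 0.057 without baseline 355), the phase I list (up to 0.15 without t0 359 or 375 or t2 339) and the muscle list (up to 0.075 without t0 357, 359 or 367 or t2 339). It moved Cckar to −6.77 (t0 359) and Tpsb2 to −2.56 (baseline 355). Without baseline 345, Cd5 stood at 4.80, Tigit at 7.36 and Tnnc2 at 8.47 (5.85 without another library). These calls were kept. Genes named for moving against their lists, here and at the other times, were chosen after their values were seen.

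At t2, the question was what remained 2 months after the exposure ended. Lists of club cells (lower) and of squamous epithelium, protein folding and skeletal muscle (higher) passed with the preset correlation between genes but not with an estimated one. The club-cell dehydrogenase Aldh1a7 fell from 360 ± 63 CPM (SD, n = 6) to 154 ± 31 (n = 5), Cckar from 174 ± 37.3 to 14.7 ± 6.59, and muscle myoglobin, Mb, rose from 0.333 ± 0.201 to 22.8 ± 22.7. Of 14847 genes, 2953 changed (edgeR): 1657 rose and 1296 fell, 978 at least 2-fold, and 11 of 46 lists passed (17 without baseline 344), and 0 with an estimated correlation (5 at an unadjusted p under 0.05). With library totals alone 2551 changed and 80.3% of them rose, against 56.1%, and the median of all genes moved to 0.12. With quantile normalization 45.6% rose. For 37 of the 42 called genes named, t2 and baseline libraries did not overlap.

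Eef1a2 (adjusted p = 0.00014) had 1 count at baseline and 1173 at t2, a ratio of 1350 (95% exact interval 242 to 53300, and its log2 value moved from 9.65 to 10.86 without baseline 343), and Pvalb (adjusted p = 0.0031) was at least 1280-fold higher (612-fold without t2 360). Slc44a5 (−5.45 ± 0.91, 0.00023) and Bex4 (−4.96 ± 0.88, 0.00043) fell. In the skeletal muscle list, 14 of 15 rose and 1 fell (14 and 1 over the list alone), median 7.74, adjusted p = 3.8e-10 (0.46 with an estimated correlation). Mb (6.08 ± 0.92, 1e-04), Tnni2 (5.70 ± 0.88, 0.00012) and Tnnc2 (9.56 ± 1.76, 0.00074) rose and Myh7 (−2.26 ± 0.61, 0.011) fell. Tnnc2 stood at 11.09 without baseline 345. Among genes of club cells, 8 of 14 fell (13 over the list alone), median −1.02, adjusted p = 3.1e-08 (0.17 with an estimated correlation). Aldh1a7 (−1.22 ± 0.17, 3.8e-05), Cckar (−3.56 ± 0.56, 0.00013) and Scgb3a2 (−1.90 ± 0.35, 0.00063) led. Of squamous epithelium genes, 9 of 15 rose (10 over the list alone), median 2.23, adjusted p = 4.4e-07 (0.27 with an estimated correlation). Serpinb2 (5.80 ± 0.64, 3.8e-06), Tgm1 (2.76 ± 0.36, 1.2e-05) and Krt4 (2.08 ± 0.30, 4e-05) led. In the basal cell list, 6 of 18 rose and 1 fell (6 and 1 over the list alone), median 0.38, adjusted p = 0.028 (0.83 with an estimated correlation). Krt14 (3.84 ± 0.49, 1.3e-05) and Krt17 (2.25 ± 0.40, 0.00045) rose and Pdpn (−0.86 ± 0.30, 0.039) fell. Among genes of tuft cells, the chemosensory cells of the airway, 6 of 10 fell (7 over the list alone), median −1.13, adjusted p = 0.00027 (0.46 with an estimated correlation). The taste signalling genes Gng13 (−2.57 ± 0.49, 0.00074) and Gnat3 (−1.90 ± 0.41, 0.0024) led. For neuroendocrine cell genes, 6 of 12 rose (7 over the list alone), median 1.05, adjusted p = 0.00055 (0.53 with an estimated correlation). Chga (1.60 ± 0.29, 0.00061) led. The call was lost without 1 library for Pdpn (adjusted p up to 0.11 without baseline 345, 352, 355 or 356 or t2 334, 339 or 347) and the basal list (up to 0.11 without baseline 355 or t2 339 or 358).

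Of unfolded protein response genes, 9 of 17 rose (10 over the list alone), median 0.50, adjusted p = 1.5e-05 (0.46 with an estimated correlation). Sdf2l1 (1.37 ± 0.19, 3.7e-05) and the disulfide isomerase Pdia4 (0.72 ± 0.13, 0.00052) led. For ribosomal proteins, whose many pseudogenes share reads, 20 of 45 fell (22, and 2 that rose, adjusted over the list alone), median −0.54, adjusted p = 2.1e-06 (0.83 with an estimated correlation). Rpl5 (−1.0 ± 0.18, 0.00047) and Rps20 (−1.51 ± 0.28, 0.00066) led. Of respiratory chain genes, 13 of 44 fell and 1 rose (13 and 1 over the list alone), median −0.20, adjusted p = 0.00055 (0.83 with an estimated correlation). Cox7b (−0.77 ± 0.13, 0.00039) and Uqcrh (−0.77 ± 0.14, 0.00042) fell, and Ndufs7 (0.52 ± 0.16, 0.021) rose. Of phase II enzymes, 9 of 28 fell (10 over the list alone), median −0.57, adjusted p = 2e-04 (0.6 with an estimated correlation). Gsta3 (−1.35 ± 0.20, 7.8e-05) and the sulfotransferase Sult1d1 (−1.15 ± 0.20, 0.00041) led. Of phase I xenobiotic enzymes, 9 of 26 fell (10 over the list alone), median −0.35, adjusted p = 0.00057 (0.6 with an estimated correlation). Cyp2a5 (−1.68 ± 0.25, 5.7e-05), which shares reads with Cyp2a4 led. Lists that did not pass were led by Srebf2 (0.61 ± 0.12, 0.0012) for cholesterol synthesis, Cry1 (1.05 ± 0.18, 0.00035) for the clock, Ereg (5.43 ± 0.88, 0.00017) for EGFR ligands and Col1a1 (−1.59 ± 0.39, 0.0052) for fibroblasts. Hypoxia, goblet, STAT3 and submucosal gland lists were led by Pfkp (0.87 ± 0.15, 0.00028), Clca3a1 (2.83 ± 0.46, 2e-04), Il4ra (0.86 ± 0.20, 0.0033) and Ltf (1.16 ± 0.25, 0.0022). For p53 targets, antimicrobial proteins, interferon response and NF-kB they were Cdkn1a (1.04 ± 0.23, 0.0027), Pigr (−1.0 ± 0.19, 0.00084), Ifi44 (−1.48 ± 0.43, 0.018) and Nfkb1 (0.42 ± 0.12, 0.011). Without t2 339, Nfkb1 stood at 0.26 (adjusted p = 0.049), and the call was lost for Ifi44 (adjusted p up to 0.051 without t2 334) and Ndufs7 (up to 0.05 without baseline 343).

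4 months after exposure, club-cell transcripts were lower than at baseline. Lists of drug-metabolizing enzymes (lower) and of cholesterol synthesis, EGFR ligands, squamous epithelium and neuroendocrine cells (higher) passed with the preset correlation but not with an estimated one. Aldh1a7 stood at 123 ± 18.3 CPM (SD, n = 6) against 360 ± 63 (n = 6) at baseline, Cckar at 9.94 ± 6.25 against 174 ± 37.3, and the EGFR ligand epiregulin, Ereg, at 11.8 ± 17.9 against 0.194 ± 0.131. Ereg was at 48.2 in t4 336 and at 2.35 to 8.13 in the other t4 libraries. Of 14847 genes, 2907 changed (edgeR): 1488 rose and 1419 fell, 873 at least 2-fold, and 19 of 46 lists passed (1 with an estimated correlation). With library totals alone 2120 changed and 71.2% of them rose, against 51.2%. For 37 of the 48 called genes named, though not Cnfn or Cd68, t4 and baseline libraries did not overlap.

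Pvalb (adjusted p = 0.018) was at least 203-fold higher (165-fold without baseline 345), and Tnnc2 (6.88 ± 1.74, 0.0076) rose (8.41 without baseline 345). Cnfn (6.46 ± 1.31, 0.0013) stood at 10.06 (adjusted p = 0.0017) without baseline 352. Bex4 (−4.49 ± 0.80, 0.00035) fell. The chitinase-like Chil4 (−5.21 ± 1.60, 0.024), which shares reads with Chil3, averaged 229 ± 529 and 6.11 ± 5.28 CPM and stood at −1.07 (0.54) without baseline 345, and Retnla (−4.48 ± 1.05, 0.0045) at −2.04 (0.045) without it. Among genes of club cells, 12 of 14 fell (13 over the list alone), median −1.28, adjusted p = 2.8e-13 (0.012 with an estimated correlation). Aldh1a7 (−1.55 ± 0.16, 8.5e-07), Cckar (−4.13 ± 0.53, 1.2e-05) and Cldn10 (−2.41 ± 0.42, 0.00033) led. For neuroendocrine cell genes, 9 of 12 rose (9 over the list alone), median 1.35, adjusted p = 3.3e-06 (0.36 with an estimated correlation). Chga (1.73 ± 0.29, 0.00017) and the peptide gene Calca (1.83 ± 0.35, 0.00068) led. Of squamous epithelium genes, 6 of 15 rose (8 over the list alone), median 1.53, adjusted p = 4.9e-06 (0.36 with an estimated correlation). Serpinb2 (4.71 ± 0.62, 1.5e-05) and the desmosomal Dsg3 (3.31 ± 0.54, 0.00015) led. Among genes of tuft cells, 5 of 10 fell (5 over the list alone), median −0.83, adjusted p = 0.00092 (0.45 with an estimated correlation). Gnat3 (−1.97 ± 0.39, 0.00096) led. In the ciliated cell list, 4 of 30 rose (3 over the list alone), median 0.29, adjusted p = 0.047 (0.77 with an estimated correlation). Rfx2 (0.93 ± 0.18, 0.00082) led. The call was lost without 1 library for Chil4 (adjusted p up to 0.54 without baseline 345 or t4 340) and the ciliated list (up to 0.13 without baseline 343 or 352, t2 339 or t4 335, 340, 348 or 377).

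Of phase I xenobiotic enzymes, 10 of 26 fell and 1 rose (11 and 1 over the list alone), median −0.51, adjusted p = 3.4e-06 (0.36 with an estimated correlation). Aox3 (−1.33 ± 0.18, 2e-05) and Cyp2j6 (−0.94 ± 0.16, 0.00018) fell and Cyp2s1 (0.66 ± 0.23, 0.042) rose. Of phase II enzymes, 12 of 28 fell (13 over the list alone), median −0.62, adjusted p = 3.3e-06 (0.36 with an estimated correlation). Gsta3 (−1.33 ± 0.19, 3.3e-05) and Gstt3 (−1.23 ± 0.19, 5.9e-05) led. In the ribosomal protein list, 20 of 45 fell (23 over the list alone), median −0.55, adjusted p = 2.6e-09 (0.56 with an estimated correlation). Rpl5 (−0.92 ± 0.17, 0.00045) and Rpl7 (−0.83 ± 0.16, 0.00065) led. Of respiratory chain genes, 13 of 44 fell (18 over the list alone), median −0.29, adjusted p = 3.3e-06 (0.56 with an estimated correlation). Ndufa9 (−0.78 ± 0.15, 0.00064) led. Of cholesterol synthesis genes, 9 of 18 rose (12, and 1 that fell, adjusted over the list alone), median 0.48, adjusted p = 2.4e-05 (0.36 with an estimated correlation). The sterol regulator Srebf2 (0.87 ± 0.12, 1.6e-05) led. Of unfolded protein response genes, 4 of 17 rose (7 over the list alone), median 0.40, adjusted p = 0.002 (0.58 with an estimated correlation). Creld2 (0.60 ± 0.12, 0.0013) and Sdf2l1 (0.88 ± 0.19, 0.0016) led. Of interferon response genes, 7 of 27 fell and 1 rose (10 and 1 over the list alone), median −0.47, adjusted p = 0.0027 (0.7 with an estimated correlation). The RNA sensor Ddx58 (−0.89 ± 0.18, 0.0013) and Ifi44 (−1.86 ± 0.41, 0.0027) fell, and Mx1 (0.65 ± 0.19, 0.019) rose. Without 1 library the call was lost for Cyp2s1 (adjusted p up to 0.088 without baseline 343, 345, 352 or 356 or t4 335, 336, 340, 348 or 371) and Mx1 (up to 0.058 without t4 371).

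Of EGFR ligands and MAPK feedback genes, 7 of 22 rose (11 over the list alone), median 0.76, adjusted p = 0.035 (0.7 with an estimated correlation). Ereg (5.90 ± 0.88, 5.1e-05) and amphiregulin, Areg (4.73 ± 0.88, 0.00062) led. Without t4 336 Ereg stood at 4.54 (8.8e-05) and Areg at 3.28 (0.002). For NF-kB and cytokine genes, 4 of 21 rose (4 over the list alone), median 0.74, adjusted p = 0.034 (0.7 with an estimated correlation). Nfkb2 (0.86 ± 0.22, 0.0082) led. In the macrophage list, 4 of 19 rose (4, and 1 that fell, adjusted over the list alone), median 0.66, adjusted p = 0.043 (0.7 with an estimated correlation). Cd68 (1.41 ± 0.35, 0.0065) led. Among fibroblast genes, 7 of 14 fell (7 over the list alone), median −0.89, adjusted p = 0.00092 (0.64 with an estimated correlation). Col1a1 (−1.78 ± 0.37, 0.0014) and Mgp (−1.73 ± 0.36, 0.0017) led. Of smooth muscle genes, 4 of 9 rose (4 over the list alone), median 1.44, adjusted p = 0.043 (0.7 with an estimated correlation). Tagln (1.51 ± 0.50, 0.032) led. In the skeletal muscle list, 13 of 15 rose (14, and 1 that fell, adjusted over the list alone), median 4.68, adjusted p = 4.6e-06 (0.58 with an estimated correlation). Mylk2 (adjusted p = 0.0071) had 3 counts at baseline and 99 at t4, a ratio of 41.7 (95% exact interval 13.9 to 206), and its log2 value moved from 5.22 to 7.50 without baseline 345. Of erythroid genes, 1 of 8 rose (8 over the list alone), median 4.24, adjusted p = 0.023 (0.7 with an estimated correlation). Hba-a1 (4.49 ± 1.58, 0.047), a haemoglobin gene with near-identical copies, stood at 2.33 (0.25) without t4 371. Hbb-bt and Hbb-b2 had equal counts in every group, so the 8 members are not all separate measurements. Calls ended without 1 library for Tagln (adjusted p up to 0.098 without baseline 343, 344, 345 or 355 or t4 340 or 377), Hba-a1 (up to 0.25 without any of the 6 baseline libraries, t2 334, 347, 358 or 360, t4 335, 336, 340 or 371 or t6 365), the EGFR list (up to 0.23 without baseline 352 or 355, t2 339 or t4 336), NF-kB (up to 0.1 without baseline 352 or 355 or t4 336 or 340), macrophages (up to 0.15 without baseline 343, 352 or 355, t2 339 or t4 348 or 377) and smooth muscle (up to 0.18 without baseline 345, 352 or 355, t2 339 or t4 336, 340 or 377). Lists that did not pass were led by Cd22 (3.05 ± 0.76, 0.0066), Krt14 (3.53 ± 0.48, 2e-05), Mybl2 (1.34 ± 0.36, 0.011), Col2a1 (−3.11 ± 0.77, 0.0058) and Per2 (1.11 ± 0.21, 0.00056) for B cells, basal cells, the cell cycle, cartilage and the clock. For hypoxia, goblet cells, p53 targets, antimicrobial proteins and STAT3 targets they were Pfkp (0.94 ± 0.14, 5.2e-05), Clca3a1 (3.05 ± 0.45, 5.2e-05), Ccng1 (−0.93 ± 0.17, 0.00054), Pigr (−1.30 ± 0.18, 2.2e-05) and Il4ra (0.84 ± 0.19, 0.0028).

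At t6, the time lung tumours develop, club-cell transcripts were lower than at baseline. Tuft cell, interferon and heat shock lists (lower) and cholesterol synthesis, squamous and skeletal muscle lists (higher) passed with the preset correlation but not with an estimated one. Aldh1a7 fell from 360 ± 63 CPM (SD, n = 6) to 131 ± 27.7 (n = 5), Cckar from 174 ± 37.3 to 16.7 ± 2.86, the taste G protein Gnat3 from 15 ± 7.74 to 2.5 ± 0.922 and the chaperone Hspa8 from 1870 ± 517 to 630 ± 177. Krt4 stood at 446 ± 144 against 129 ± 51.4, and Mb at 46 ± 48.9 against 0.333 ± 0.201. Of 14847 genes, 1311 changed (edgeR): 674 rose and 637 fell, 593 at least 2-fold, and 20 of 46 lists passed (1 with an estimated correlation). With library totals alone 833 changed and 72.0% of them rose, against 51.4%, and without the doubted libraries (357, 339, 371 and 349) 1329 changed and 62.2% rose. Without t2 339, 2057 genes changed. For 31 of the 42 called genes named, though not Cnn1 or C1qa, t6 and baseline libraries did not overlap.

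Myh1 (10.92 ± 1.85, 0.00047) and Tnnc2 (10.17 ± 1.77, 0.00059), of fast muscle, rose, and Pvalb (adjusted p = 0.0035) was at least 2160-fold higher (1150-fold without t6 366). Fbn2 (−4.36 ± 0.82, 0.001) and the cardiac myosin Myh6 (−5.21 ± 1.62, 0.042) fell. Leaving out 1 library moved Myh1 to 13.84 (baseline 356), Tnnc2 to 11.70 (baseline 345) and Fbn2 to −5.69 (t6 366), with calls kept. Chil4 (−6.09 ± 1.81, 0.036) averaged 229 ± 529 and 3.39 ± 2.96 CPM and stood at −1.94 (0.36) without baseline 345. In the skeletal muscle list, 14 of 15 rose and 1 fell (14 and 1 over the list alone), median 7.83, adjusted p = 4.2e-16 (0.16 with an estimated correlation). Mb (7.09 ± 0.95, 3e-05) and Tnni2 (5.96 ± 0.88, 8.8e-05) rose and Myh7 (−2.18 ± 0.60, 0.023) fell. Of smooth muscle genes, 6 of 9 rose (7 over the list alone), median 1.74, adjusted p = 0.00014 (0.39 with an estimated correlation). Des (3.94 ± 0.91, 0.0068) led, and Cnn1 (2.15 ± 0.58, 0.019) stood at 1.34 (0.12) without t6 368. Among genes of club cells, 9 of 14 fell (12 over the list alone), median −1.17, adjusted p = 2.2e-12 (0.026 with an estimated correlation). Aldh1a7 (−1.45 ± 0.17, 6.4e-06) and Cckar (−3.38 ± 0.55, 0.00024) led. Among genes of tuft cells, 6 of 10 fell (8 over the list alone), median −1.63, adjusted p = 9.2e-09 (0.12 with an estimated correlation). Gnat3 (−2.58 ± 0.43, 0.00025) and Rgs13 (−2.81 ± 0.50, 0.00056) led. Of squamous epithelium genes, 6 of 15 rose (6 over the list alone), median 0.50, adjusted p = 2e-06 (0.19 with an estimated correlation). Serpinb2 (4.88 ± 0.63, 2e-05) and Krt4 (1.79 ± 0.29, 0.00024) led. For neuroendocrine cell genes, 3 of 12 rose (4 over the list alone), median 0.86, adjusted p = 0.00027 (0.39 with an estimated correlation). Scg2 (2.07 ± 0.45, 0.0035) and Chga (1.17 ± 0.29, 0.011) led. In the submucosal gland list, 1 of 9 rose (4 over the list alone), median 1.12, adjusted p = 0.012 (0.45 with an estimated correlation). Lactoferrin, Ltf (0.97 ± 0.25, 0.014) led. The call was lost without 1 library for Myh6 (adjusted p up to 0.092 without baseline 352, 355 or 356 or any of the 5 t6 libraries), Chil4 (up to 0.36 without baseline 345 or any of the 5 t6 libraries), Myh7 (up to 0.058 without baseline 352 or 355 or t6 349 or 368), Cnn1 (up to 0.12 without t6 368) and the gland list (up to 0.058 without t6 368).

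Of interferon response genes, 12 of 27 fell (16, and 1 that rose, adjusted over the list alone), median −0.79, adjusted p = 2.1e-09 (0.39 with an estimated correlation). Irf9 (−0.85 ± 0.17, 0.0022), Ddx58 (−0.94 ± 0.19, 0.0023) and Oas1a (−1.04 ± 0.21, 0.0023) led. Of heat shock genes, 8 of 13 fell (11 over the list alone), median −1.04, adjusted p = 3.6e-08 (0.39 with an estimated correlation). Hspa8 (−1.57 ± 0.30, 0.001) and Hspa1a (−3.16 ± 0.75, 0.0078), which shares reads with Hspa1b led. Of cholesterol synthesis genes, 7 of 18 rose (12 over the list alone), median 0.52, adjusted p = 6.4e-08 (0.16 with an estimated correlation). Msmo1 (1.47 ± 0.26, 0.00065) and Srebf2 (0.59 ± 0.12, 0.0025) led. In the ribosomal protein list, 8 of 45 fell (12 over the list alone), median −0.33, adjusted p = 0.00011 (0.58 with an estimated correlation). Rpl24 (−1.01 ± 0.26, 0.014) led. Of respiratory chain genes, 3 of 44 fell (0 over the list alone), median −0.15, adjusted p = 0.0032 (0.58 with an estimated correlation). Ndufa9 (−0.54 ± 0.15, 0.027) led. At an unadjusted p, 10 passed, and 3 each by DESeq2 and limma. Of phase II enzymes, 4 of 28 fell (6, and 1 that rose, adjusted over the list alone), median −0.40, adjusted p = 0.0027 (0.54 with an estimated correlation). Ugt1a6a (−1.40 ± 0.26, 9e-04), of a gene cluster with shared exons, and Gsta3 (−0.92 ± 0.20, 0.004) led. Of phase I xenobiotic enzymes, 4 of 26 fell (6, and 1 that rose, adjusted over the list alone), median −0.23, adjusted p = 0.013 (0.57 with an estimated correlation). Cyp4b1 (−0.81 ± 0.19, 0.0058) and Aox3 (−0.83 ± 0.19, 0.0059) led. In the cell cycle list, 2 of 33 fell (1 over the list alone), median −0.41, adjusted p = 0.015 (0.71 with an estimated correlation). The mitotic kinase Plk1 (−0.77 ± 0.21, 0.023) led. Without 1 library the call was lost for Rpl24 (adjusted p up to 0.052 without baseline 356), Ndufa9 (up to 0.083 without baseline 344 or 356 or t6 349 or 368), Plk1 (up to 0.064 without baseline 343 or t6 341 or 368), ribosomal proteins (up to 0.053 without t6 368), the respiratory chain (up to 0.19 without t6 368), phase I enzymes (up to 0.096 without t6 368) and the cell cycle (up to 0.099 without baseline 343 or 345 or t6 366).

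In the macrophage list, 1 of 19 rose (1 over the list alone), median 0.72, adjusted p = 0.00063 (0.54 with an estimated correlation), and the called member was complement C1qa (0.83 ± 0.24, 0.026). Among MHC class II genes, 1 of 10 rose (1 over the list alone), median 0.75, adjusted p = 0.0084 (0.54 with an estimated correlation), the member being H2-Ob (1.55 ± 0.50, 0.049). Of B and plasma cell genes, 4 of 11 rose (5, and 1 that fell, adjusted over the list alone), median 1.37, adjusted p = 0.0087 (0.39 with an estimated correlation). Cd79a (4.57 ± 1.07, 0.0068) led. Erythroid genes passed as a list although 0 of 8 were called by edgeR, DESeq2 or limma (6 at an unadjusted p under 0.05), median 3.49, adjusted p = 0.012 (0.59 with an estimated correlation), and the first was Hba-a1 (3.63 ± 1.54, 0.15). Hba-a1 stood at 1.42 (0.66) without t6 349. The endothelial list passed with 0 of 11 called by edgeR (2 at an unadjusted p under 0.05, and 1 each by DESeq2 and limma), median 0.63, adjusted p = 0.047 (0.58 with an estimated correlation), and its first gene was Cldn5 (1.96 ± 0.64, 0.052). In both lists 0 were called adjusted over the list alone. Calls ended without 1 library for C1qa (adjusted p up to 0.1 without baseline 343 or 355 or t6 349 or 368), H2-Ob (up to 0.1 without baseline 343, 344, 352, 355 or 356, t0 332 or 357, t2 334, 347 or 360, t4 335, 348 or 371 or any of the 5 t6 libraries), the B cell list (up to 0.056 without t6 368), the erythroid list (up to 0.091 without t6 349) and the endothelial list (up to 0.24 without baseline 345, 352 or 355, t0 332, 359 or 375, t2 358 or t6 341 or 368). Cldn5 was called without baseline 344, t2 339 or t6 349. Lists that did not pass were led by Ereg (3.76 ± 0.85, 0.0051) for EGFR ligands, Clca3a1 (3.30 ± 0.47, 4.4e-05) for goblet cells and Reg3g (−1.36 ± 0.23, 0.00025) for antimicrobial proteins.

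From t0 to t2, over the first 2 months after the exposure ended, transcripts of p53 targets fell. Ciliated and club cell lists (higher) and immune, cell cycle and basal cell lists (lower) passed with the preset correlation but not with an estimated one. Scgb1a1 rose from 701 ± 390 CPM (SD, n = 6) to 19000 ± 6510 (n = 5). Of 14847 genes, 4445 changed (edgeR): 2330 rose and 2115 fell, 2367 at least 2-fold, and 18 of 46 lists passed (1 with an estimated correlation). With library totals alone 3749 changed and 44.8% of them rose, against 52.4%. For 44 of the 56 called genes named, t0 and t2 libraries did not overlap. The surfactant gene Sftpb (5.21 ± 0.65, 2e-06), Cml3 (5.17 ± 0.84, 3.4e-05) and Scgb1a1 (4.76 ± 0.40, 1.4e-08) rose the most. The lipid enzyme Awat1 (adjusted p = 0.00011) was at 0 in all t2 libraries and at least 74.5-fold lower than at t0 (57.5-fold without t2 339, floor of 3 counts over the group, 0.0221 CPM), and Cyp2c65 (−6.45 ± 1.08, 4.4e-05) and Trim40 (−6.41 ± 0.90, 5.2e-06) fell (−7.55 without t2 334 and −7.78 without t2 360).

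Among genes of ciliated cells, 29 of 30 rose (29 over the list alone), median 1.99, adjusted p = 5.3e-31 (0.15 with an estimated correlation). The axonemal dynein genes Dnaic2 (2.22 ± 0.27, 1.5e-06) and Dnah9 (2.64 ± 0.33, 1.7e-06) led. Among genes of club cells, 8 of 14 rose and 1 fell (9 and 1 over the list alone), median 1.38, adjusted p = 5.6e-06 (0.22 with an estimated correlation). Scgb3a1 (2.81 ± 0.34, 1.2e-06) rose and Gabrp (−0.83 ± 0.16, 0.00019) fell. For secreted antimicrobial proteins, 9 of 16 rose and 2 fell (11 and 2 over the list alone), median 1.23, adjusted p = 0.00065 (0.22 with an estimated correlation). Ceruloplasmin, Cp (2.11 ± 0.27, 2e-06), rose, and Defb1 (−0.63 ± 0.17, 0.0055) and Slpi (−2.02 ± 0.68, 0.025) fell. In the goblet cell list, 4 of 17 rose (4 over the list alone), median 0.83, adjusted p = 0.028 (0.66 with an estimated correlation). Creb3l1 (1.23 ± 0.23, 0.00017) led. In the basal cell list, 8 of 18 fell (8 over the list alone), median −0.67, adjusted p = 0.0011 (0.6 with an estimated correlation). Dapl1 (−1.57 ± 0.24, 1.5e-05) and Krt15 (−1.92 ± 0.34, 7.6e-05) led. Of squamous epithelium genes, 5 of 15 fell (5 over the list alone), median −1.17, adjusted p = 0.016 (0.66 with an estimated correlation). Krt4 (−2.26 ± 0.31, 4.3e-06) led. In the skeletal muscle list, 6 of 15 rose (7 over the list alone), median 2.61, adjusted p = 0.0033 (0.69 with an estimated correlation). Mb (3.48 ± 0.79, 0.0014) led. Of cholesterol synthesis genes, 12 of 18 rose (13 over the list alone), median 0.74, adjusted p = 7.6e-05 (0.32 with an estimated correlation). Sqle (1.47 ± 0.20, 3e-06) and Srebf2 (0.71 ± 0.12, 5.9e-05) led. In the ribosomal protein list, 20 of 45 fell (23 over the list alone), median −0.53, adjusted p = 0.00012 (0.69 with an estimated correlation). Rps9 (−0.70 ± 0.16, 0.0017) led. Of unfolded protein response genes, 10 of 17 rose and 1 fell (10 and 1 over the list alone), median 0.54, adjusted p = 0.0053 (0.66 with an estimated correlation). Asns (1.24 ± 0.20, 3.1e-05) and Creld2 (0.74 ± 0.13, 5.6e-05) rose and Ddit3 (−0.79 ± 0.22, 0.0062) fell. Without 1 library the call was lost for Slpi (adjusted p up to 0.063 without t0 332 or t2 334 or 347), the goblet list (up to 0.17 without t0 359) and the unfolded protein list (up to 0.053 without t0 359).

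Of p53 targets, 14 of 26 fell and 1 rose (17 and 2 over the list alone), median −0.81, adjusted p = 8.1e-07 (0.032 with an estimated correlation). Ccng1 (−1.65 ± 0.19, 7e-07) and Zmat3 (−1.17 ± 0.13, 7e-07) fell, and Fas (0.80 ± 0.28, 0.032) rose. In the cell cycle list, 14 of 33 fell (19 over the list alone), median −1.06, adjusted p = 4.6e-06 (0.65 with an estimated correlation). Bub1b (−1.93 ± 0.38, 0.00028) and Mki67 (−2.03 ± 0.41, 0.00041) led. In the macrophage list, 16 of 19 fell and 1 rose (17 and 1 over the list alone), median −2.75, adjusted p = 9e-08 (0.32 with an estimated correlation). Cd68 (−3.02 ± 0.39, 2.7e-06) and the Fc receptor Fcgr1 (−2.91 ± 0.43, 8.3e-06) fell, and Lyz2 (1.33 ± 0.30, 0.0011) rose. For T and NK cell genes, 14 of 18 fell (14 over the list alone), median −3.24, adjusted p = 0.0011 (0.66 with an estimated correlation). Cd2 (−3.36 ± 0.64, 2e-04) led. Among MHC class I genes, 12 of 17 fell (12 over the list alone), median −1.25, adjusted p = 3e-06 (0.47 with an estimated correlation). Tapbp (−1.05 ± 0.14, 3.3e-06) led. Of interferon response genes, 12 of 27 fell (12 over the list alone), median −0.61, adjusted p = 0.0011 (0.73 with an estimated correlation). Ifit2 (−4.03 ± 0.69, 6.1e-05) and Mx1 (−1.01 ± 0.20, 0.00037) led. Of immune checkpoint genes, 8 of 10 fell (9 over the list alone), median −2.64, adjusted p = 0.0011 (0.32 with an estimated correlation). Ido1 (−3.76 ± 0.96, 0.0036) led. Among endothelial genes, 4 of 11 fell (5 over the list alone), median −0.70, adjusted p = 0.038 (0.69 with an estimated correlation). Vwf (−1.27 ± 0.35, 0.0072) led. The call was lost without 1 library for Fas (adjusted p up to 0.24 without t0 332, 357 or 367 or t2 339) and the endothelial list (up to 0.14 without t0 359, 374 or 375 or t2 339 or 358), and Fas stood at 0.40 without t2 339.

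Other lists did not pass. Sftpb led alveolar epithelium and Atp6v1c2 (2.59 ± 0.27, 2.9e-07) ionocytes. Lgr6 (1.86 ± 0.25, 3.8e-06), Notch1 (−1.12 ± 0.16, 7e-06) and Hlf (−1.28 ± 0.17, 3.5e-06) led Wnt, Notch and the clock. Phase I, phase II, NRF2 and DNA repair lists were led by Cyp2s1 (1.82 ± 0.24, 3e-06), Ephx1 (−1.28 ± 0.19, 7.3e-06), Fth1 (−1.09 ± 0.16, 1.2e-05) and Ogg1 (1.12 ± 0.18, 2.9e-05). Hypoxia, NF-kB, tuft, neutrophil and MHC class II lists were led by Bnip3 (1.51 ± 0.23, 1.6e-05), Birc3 (−0.97 ± 0.19, 0.00026), Alox5ap (−1.93 ± 0.37, 0.00022), Il1r2 (−2.70 ± 0.78, 0.0096) and H2-Ab1 (−1.91 ± 0.49, 0.0041). Smooth muscle, mast cell, STAT3, respiratory chain and EGFR lists were led by Cnn1 (2.32 ± 0.59, 0.0037), Tpsb2 (2.59 ± 0.70, 0.0055), Pim1 (−0.92 ± 0.24, 0.0046), Ndufa10 (−0.41 ± 0.13, 0.015) and Ccnd1 (0.57 ± 0.17, 0.013). Ccnd1 lost its call without t2 358 (adjusted p = 0.053).

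From t0 to t6, Scgb1a1 rose and transcripts of p53 targets fell. The ciliated list (higher) and the cell cycle, interferon and squamous lists (lower) passed with the preset correlation but not with an estimated one. Scgb1a1 went from 701 ± 390 CPM (SD, n = 6) to 18200 ± 8560 (n = 5), Krt4 from 2620 ± 938 to 446 ± 144, Atg9b from 108 ± 48.4 to 5.86 ± 2.81 and Nccrp1 from 57.5 ± 41.9 to 4 ± 2.21. Of 14847 genes, 5744 changed (edgeR): 2697 rose and 3047 fell, 2722 at least 2-fold, and 17 of 46 lists passed (1 with an estimated correlation). With library totals alone 5450 changed and 35.5% of them rose, against 47.0%, and the median of all genes moved to −0.17. With haemoglobin genes left out 52.7% rose, and without the 4 doubted libraries 52.6%. For 45 of the 57 called genes named, though not Myh1, Ckmt2 or Mb, t0 and t6 libraries did not overlap. Myh1 (5.77 ± 1.32, 0.0012), from 1.29 ± 1.67 to 71.3 ± 60.6 CPM, muscle creatine kinase Ckmt2 (5.24 ± 1.29, 0.002), the protocadherin Pcdha10 (4.73 ± 0.97, 0.00034), whose cluster shares exons, and Scgb1a1 (4.70 ± 0.40, 8.9e-09) rose the most. Ckmt2 stood at 8.31 (9.2e-05) without t0 357, and at 3.9 without another library. Ubd (−6.03 ± 1.20, 0.00026) and Crnn (−5.33 ± 1.10, 0.00035) fell. Ubd stood at −4.56 (0.0014) without t0 375, and at −7.32 without another library. Spt1 (−9.85 ± 3.24, 0.019) averaged 861 ± 2110 and 0.974 ± 2.13 CPM, but its value was 5.02 (0.22) without t0 375 and −14.94 (0.016) without t6 341.

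Among genes of ciliated cells, 29 of 30 rose (29, and 1 that fell, adjusted over the list alone), median 2.12, adjusted p = 3.3e-27 (0.21 with an estimated correlation). Cfap43 (2.22 ± 0.25, 2.5e-07) and Dnah9 (2.80 ± 0.33, 5.1e-07) led. Of club cell genes, 9 of 14 rose and 1 fell (9 and 1 over the list alone), median 1.24, adjusted p = 5.8e-05 (0.32 with an estimated correlation). Scgb3a1 (3.19 ± 0.34, 1.7e-07) rose and Gabrp (−0.67 ± 0.16, 0.0013) fell. For secreted antimicrobial proteins, 6 of 16 rose and 2 fell (8 and 2 over the list alone), median 0.83, adjusted p = 0.018 (0.41 with an estimated correlation). Bpifa1 (2.72 ± 0.34, 8.4e-07) rose, and Defb1 (−0.61 ± 0.17, 0.0054) and Slpi (−2.30 ± 0.69, 0.0093) fell. In the goblet cell list, 7 of 17 rose (10, and 1 that fell, adjusted over the list alone), median 1.04, adjusted p = 0.032 (0.74 with an estimated correlation). Creb3l1 (1.04 ± 0.23, 0.00073) led. In the basal cell list, 12 of 18 fell (12 over the list alone), median −1.01, adjusted p = 6.9e-05 (0.41 with an estimated correlation). The aquaporin Aqp3 (−1.89 ± 0.31, 2.1e-05) and Krt5 (−1.76 ± 0.30, 3.9e-05) led. Of squamous epithelium genes, 8 of 15 fell (9 over the list alone), median −2.08, adjusted p = 0.0022 (0.41 with an estimated correlation). Krt4 (−2.55 ± 0.31, 7.7e-07) led. In the skeletal muscle list, 11 of 15 rose (13 over the list alone), median 3.39, adjusted p = 0.0026 (0.79 with an estimated correlation). Mb (4.50 ± 0.82, 1e-04) led. Of cholesterol synthesis genes, 14 of 18 rose (14 over the list alone), median 0.97, adjusted p = 1.6e-07 (0.23 with an estimated correlation). Sqle (1.84 ± 0.20, 1.7e-07) and Insig1 (1.72 ± 0.19, 2.7e-07) led. In the ribosomal protein list, 10 of 45 fell (7 over the list alone), median −0.30, adjusted p = 0.026 (0.81 with an estimated correlation). Rplp0 (−0.75 ± 0.17, 0.0012) led. Of heat shock genes, 6 of 13 fell (6 over the list alone), median −0.68, adjusted p = 0.038 (0.79 with an estimated correlation). Hspa8 (−1.17 ± 0.29, 0.0024) led. Calls ended without 1 library for antimicrobial proteins (adjusted p up to 0.055 without t0 359), goblet cells (up to 0.17 without t0 359 or t6 368), ribosomal proteins (up to 0.17 without t0 374 or t6 368) and heat shock (up to 0.12 without t0 359, 367 or 374, t2 339 or t6 366 or 368).

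In the cell cycle list, 27 of 33 fell (28 over the list alone), median −1.71, adjusted p = 3.1e-09 (0.41 with an estimated correlation). Foxm1 (−1.61 ± 0.23, 4.6e-06) and E2f1 (−2.84 ± 0.43, 7.5e-06) led. Of interferon response genes, 21 of 27 fell (22 over the list alone), median −1.21, adjusted p = 4.2e-08 (0.41 with an estimated correlation). Oasl1 (−2.28 ± 0.34, 9.1e-06) and Stat2 (−1.34 ± 0.21, 1e-05) led. Of p53 targets, 16 of 26 fell and 2 rose (18 and 3 over the list alone), median −0.98, adjusted p = 1.4e-07 (0.019 with an estimated correlation). Zmat3 (−1.54 ± 0.13, 1.3e-08) and Cdkn1a (−2.64 ± 0.25, 5.3e-08) fell, and Polk (0.90 ± 0.19, 0.00053) and Rrm2b (0.57 ± 0.17, 0.009) rose. Among MHC class I genes, 14 of 17 fell (17 over the list alone), median −1.46, adjusted p = 1.7e-06 (0.41 with an estimated correlation). Tapbp (−1.07 ± 0.14, 1.6e-06) led. In the macrophage list, 15 of 19 fell and 1 rose (16 and 1 over the list alone), median −2.35, adjusted p = 1.4e-05 (0.41 with an estimated correlation). Cd68 (−3.10 ± 0.39, 1.1e-06) and Laptm5 (−3.24 ± 0.48, 9.2e-06) fell, and Lyz2 (1.58 ± 0.30, 0.00013) rose. For NF-kB and cytokine genes, 12 of 21 fell (13 over the list alone), median −1.44, adjusted p = 0.002 (0.56 with an estimated correlation). Nfkb2 (−1.44 ± 0.24, 3.2e-05) led. Of immune checkpoint genes, 8 of 10 fell (8 over the list alone), median −2.51, adjusted p = 0.018 (0.41 with an estimated correlation). Cd80 (−2.69 ± 0.50, 1e-04) led.

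Lists that did not pass were led by Hopx (−1.09 ± 0.15, 3.1e-06), Atp6v1c2 (2.4 ± 0.27, 2.6e-07), Lgr6 (1.83 ± 0.25, 2.8e-06), Hey1 (1.72 ± 0.21, 6.9e-07) and Cry2 (1.65 ± 0.25, 1.1e-05) for alveolar epithelium, ionocytes, Wnt, Notch and the clock. In the phase I list, 8 of 26 rose and 4 fell (8 and 4 over the list alone), and the list did not pass. Phase II, NRF2, DNA repair and hypoxia lists were led by Ephx1 (−1.27 ± 0.19, 5.5e-06), Fth1 (−1.07 ± 0.16, 9.6e-06), Ogg1 (1.25 ± 0.18, 5.7e-06) and Bnip3 (2.29 ± 0.24, 1.2e-07). EGFR, unfolded protein, respiratory chain, submucosal gland and tuft lists were led by Dusp5 (−2.48 ± 0.72, 0.0078), Asns (0.95 ± 0.20, 5e-04), Ndufa10 (−0.59 ± 0.13, 0.00061), Dmbt1 (2.04 ± 0.47, 0.0011) and Alox5ap (−2.34 ± 0.38, 2e-05). Smooth muscle, fibroblast, mast cell, T cell, MHC class II and neuroendocrine lists were led by Cnn1 (3.11 ± 0.61, 0.00019), Col1a1 (−1.63 ± 0.39, 0.0014), Siglecf (−4.17 ± 0.96, 0.0011), Cd2 (−2.75 ± 0.62, 0.00087), Cd74 (−1.59 ± 0.51, 0.016) and Chgb (−1.31 ± 0.45, 0.022). Without 1 library the call was lost for Cd74 (−1.0, adjusted p = 0.091 without t0 375) and Chgb (up to 0.062 without t0 374 or t6 349 or 368).

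Any difference among the 5 time points was found for 8429 of 14847 genes (56.8%, edgeR). The smallest adjusted p was that of the carboxylesterase Ces2f (1.6e-13), at 2.84 CPM at baseline and 35.4 at t0. Next were the urothelial Upk1b (1.4e-12), at 116 and 1170, Sec14l4 (2.4e-11), at 79.3 and 11.9, and Trim29 (2.6e-11), at 23.5 and 150. Over the 22 exposed libraries, 4968 genes had a slope per month that differed from 0 (edgeR), 2210 upward and 2758 downward. With library totals alone 4761 had one and 30.7% of them went upward, against 44.5%. Whether changes were linear was not tested, and a step after t0 alone also gives a slope. Total counts at t0, t2, t4 and t6 were 1828, 48, 39 and 66 for Plcd4. For Chil4 they were 4173, 41347, 824 and 519. The largest slopes (log2 per month ± SE, adjusted p) were those of Myh1 (0.76 ± 0.22, 0.011) and Pcdha12 (0.74 ± 0.15, 0.0011) upward, and of Spt1 (−1.77 ± 0.45, 0.0042), Chil4 (−1.15 ± 0.40, 0.031), Ubd (−1.02 ± 0.19, 0.00049) and Plcd4 (−0.85 ± 0.14, 0.00014) downward. Calls ended without 1 library for Spt1 (adjusted p up to 0.18 without t0 375) and Chil4 (up to 0.065 without t6 349, 365, 366 or 368), and the slope of Chil4 was −0.74 (0.018) without t2 334.

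Of the genes called at t0, 763 kept their direction at t6 (402 higher and 361 lower). Pvalb (above 0 in 3 of 6 at t0), Atg9b, Nccrp1 and Cnfn led. Another 4102 were no longer called at t6 and had moved back from t0 (2122 higher at t0 and 1980 lower). Among them were Spt1, high at t0 only in 375, the chemokine receptor Cxcr1 (7.20 ± 1.05, 4.7e-06) and Gpnmb (6.75 ± 0.79, 3.1e-07). A further 327 were called at t6 and against t0 but not at t0, 171 higher and 156 lower. Ckmt2 (8.59 ± 1.60, 9e-04) led, at 7.25 without t6 368 and 9.85 without another library. Next was Hfe2 (adjusted p = 0.0024, ratio 219, 95% exact interval 74.6 to 1060). From baseline to t6 counts were 4, 40, 288, 30 and 1949 for Ckmt2 and 3, 29, 175, 31 and 675 for Hfe2. Like the muscle list, both were higher at t2 than at t4. Without t2 339, 1195 kept their direction and 492 were late. These comparisons share the baseline libraries. Independent lists of these sizes would share 157 rises and 142 falls, and simulated unchanged groups shared 0. With 3 different baseline libraries for each time (20 splits) fewer genes were called, and a median of 281 (216 to 449) kept their direction, where independent lists would share 91.3 (65.1 to 161). Moves back numbered 3577 (3344 to 3778) and late changes 142.5 (98 to 258) in those splits. The splits kept the same t0 and t6 libraries in both tests, so they do not address that sharing. Across genes, which are not independent replicates, changes correlated at 0.54 (t0 and t2), 0.51 (t0 and t4), 0.44 (t0 and t6), 0.80 (t2 and t4), 0.69 (t2 and t6) and 0.78 (t4 and t6), against 0.46 to 0.50 for simulated unchanged groups. The covariances were 0.280, 0.244, 0.207, 0.235, 0.203 and 0.211 in the same order, against a simulated 0.030 to 0.031, and 0.257, 0.219, 0.183, 0.212, 0.181 and 0.189 with split baselines.

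**Figure D3:**
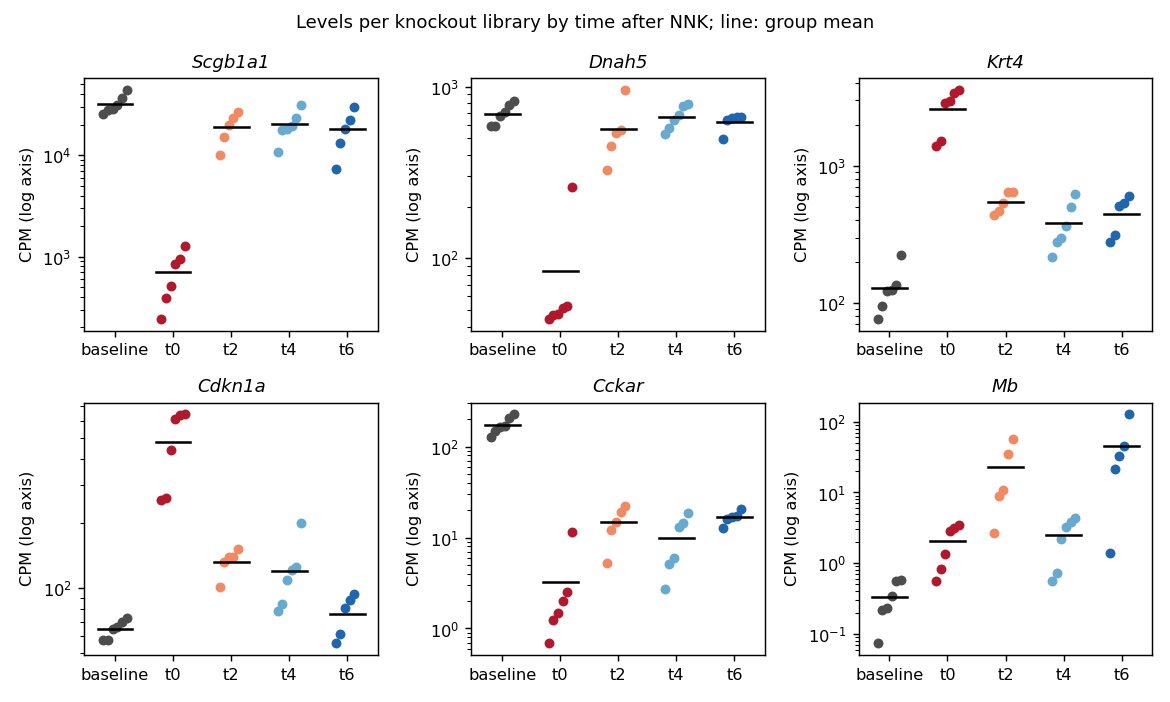
CPM of Scgb1a1, Dnah5, Krt4, Cdkn1a, Cckar and Mb in each knockout library, on a log axis, by group, with a line at the group mean. Scgb1a1 means were 32300 at baseline, 701 at t0 and 18200 at t6.

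**Figure D4:**
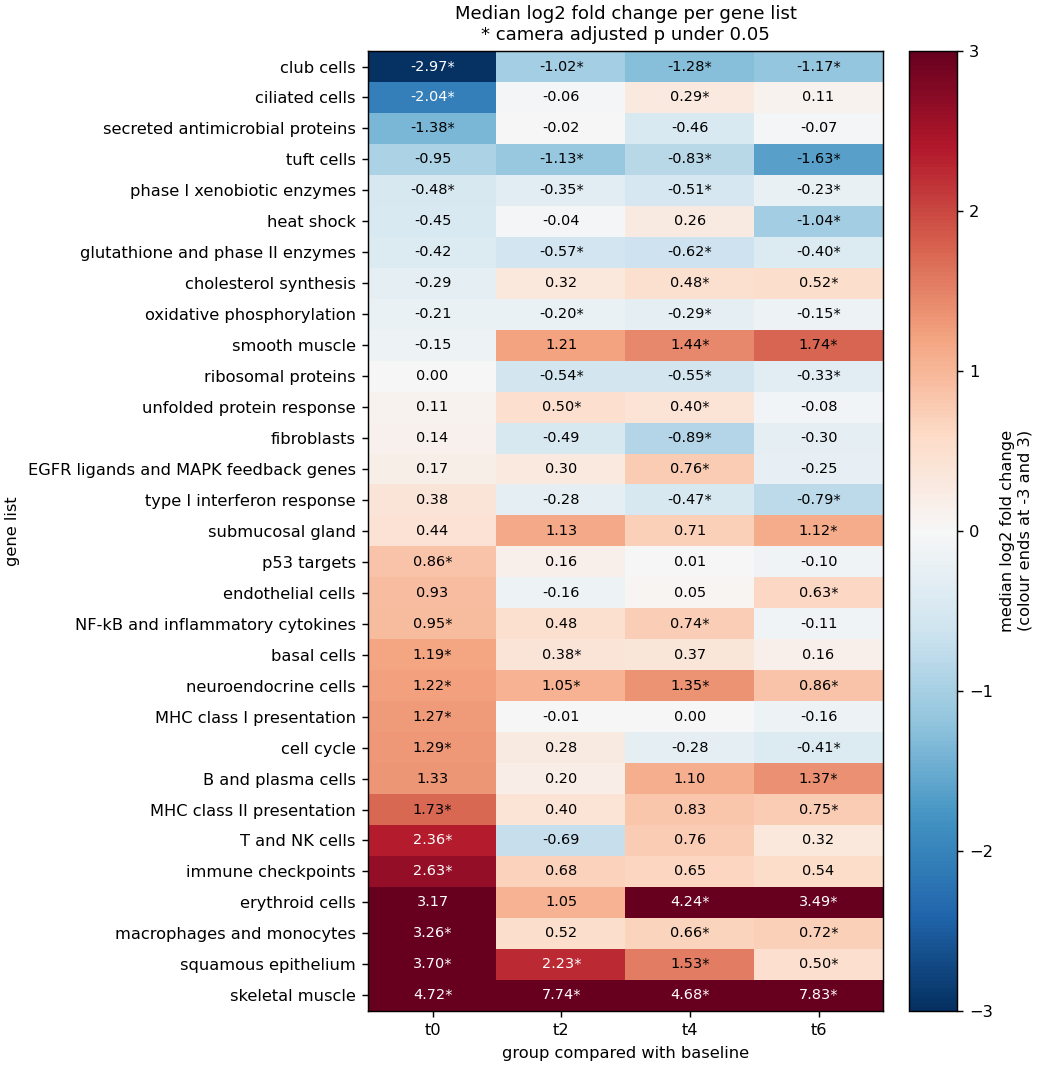
Median log2 fold change against baseline at t0, t2, t4 and t6 of the 31 lists that passed in at least 1 of these comparisons, with an asterisk where the adjusted p with the preset correlation was under 0.05. The ciliated list was at −2.04 at t0, and the skeletal muscle list was at 7.83 at t6.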

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

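The tests of the 3 patterns below and the splits of the libraries were chosen after the results were seen.

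Skeletal muscle transcripts were high in exposed libraries: summed CPM of the list without Myh7 was 2.77 to 11.8 at baseline, 7.53 to 299 at t0, 148 to 2140 at t2, 20.3 to 133 at t4 and 22.5 to 2480 at t6. A single library was argued against, as each library at t2, t4 and t6 lay above the highest baseline sum. The highest adjusted p of the list at t6 with any library left out was 4.8e-13 with the preset correlation, but with an estimated one the list did not pass at t6 (0.16, all libraries). A smaller share of epithelial cells as the whole cause, which would raise every other cell type alike, was argued against. The medians at t6 of 5 other tissue lists reached at most 1.74 (smooth muscle), against 7.83 for muscle. Fibroblasts stood at 0.14, −0.49, −0.89 and −0.30 at t0, t2, t4 and t6 (upper quartiles 0.46, 0.22, −0.36 and 0.51), against lower quartiles of 3.30, 5.98, 3.01 and 6.60 for muscle. Blood and immune lists, not among the 5, rose closer to muscle (erythroid 3.49 at t6 and 4.24 at t4, macrophages 3.26 at t0), and changes in these cells stay open. Muscle tissue carried into the brushings is a candidate explanation, with a median Spearman correlation of 0.87 over 105 pairs of members (lowest −0.30, and a median of −0.08 for Myh7 with the others). Age and exposure, which the design does not separate, remain untested.

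The library labelled t2 339 had 14283 genes above 0 (others 17234 to 18088), a median correlation of 0.919 with its group (0.961 to 0.973), 1.76% haemoglobin (0.695 to 0.856) and 238 Gprc5a counts (11 to 36). Lower depth was argued against, as its total of 29.5 M lay above the median of 26.6 M. Of genes predicted at 20 counts or more, 8.69% were at 0, against at most 0.792% in the other 27, which is consistent with a library of low complexity. Wild-type material stays open, with Gprc5a at 8.06 CPM against at most 2.88, as no other gene was tested for telling the genotypes apart. No biological explanation was tested.

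Club and ciliated transcripts fell at t0. Scaling set by a few abundant genes was argued against, since the median of the 44 genes lay between −2.28 and −1.86 over 4 scalings. A smaller share of club or of ciliated cells stays open as the cause. From the list median, 9 of 14 and 4 of 30 members departed by over 3 of their SE, but their expression in other cells was not tested. The exposure, which the design gives, remains open as a biological source.

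By the gap to the nearest library, a value stood apart in 24 of 90 groups of values, 4 of them in t2 339 and 9 for single genes named for their changes. The limit used lets about 1 in 20 groups stand apart by chance for normal values, a rate not measured for these values, which are related. Baseline 344 had 16686 genes above 0 (others 17947 to 18478) and 1.52% haemoglobin (0.0168 to 0.43). Haemoglobin was 22.8% in t0 357 (0.0181 to 0.883), 25.5% in t4 371 (0.373 to 3.06), 15.3% in t6 349 (0.453 to 1.5) and 21.2% in wild-type 454 (0.159 to 5.3), and wild-type 454 and 289 (5.3%) lay above the highest knockout baseline value. The t0 library 359 lay at 30.4 on component 1 (72.8 to 91.6), with a median correlation of 0.939 (0.959 to 0.964), Dnah5 at 261 CPM (44.3 to 52.6) and Cckar at 11.6 (0.684 to 2.51). The median correlation was 0.941 in t6 368 (0.97 to 0.972), the total was 30 M in t4 335 (15.6 to 20.7), and wild-type 295 had 17055 genes above 0 (23279 to 26250). Spt1 was at 5170 CPM in t0 375 (0 to 0.0827) and 4.78 in t6 341 (0 to 0.0919). In baseline 352, Cnfn was at 0.388 CPM (others 0) and Krt14 at 18.9 (3.31 to 4.53). Chil4 was at 1310 in baseline 345 (0.327 to 54.9), Hspa8 at 2840 in baseline 356 (1420 to 1930) and Ereg at 48.2 in t4 336 (2.35 to 8.13). Between t0 and t2 the change differed for 4445 genes, and between t0 and t6 for 5744 (edgeR).

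For each count of genes, 1 of the 100 splits drawn (of 462 for each pair of groups), the real one, gave as many, so chance can be excluded at a limit of 1 in 20 splits, though for t6 against t0 another split came close. The highest of the others was 1736 at t0 (real 6761), 1836 at t2 (2953), 762 at t4 (2907), 72 at t6 (1311), 3310 for t2 against t0 (4445), 5634 for t6 against t0 (5744), 497 for the F test (8429) and 1 for the trend (4968).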

How the results depend on the processing

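Tests with DESeq2, limma on CPM, library totals, haemoglobin genes left out and the 4 doubted libraries left out were chosen after the data were seen. Over settings that kept every library or left out the 4, 216 of 238 values of 24 main results were kept, meaning that counts stayed within 1.5 times, and correlations and the wild-type value within their spread. For t4, 1918 genes changed at least 1.5-fold, and 4371 were called with only the groups compared. Library quality weights gave 5377 genes at t4, 3795 at t6, 1901 lasting and 750 late genes and 13 lists at t6. Library totals alone gave 833 genes at t6 and 213 late genes. With an estimated correlation in camera 2 lists were called at t0, 0 at t2 (5 at an unadjusted p), 1 at t4, 1 at t6, 1 for t2 against t0 and 1 for t6 against t0, and fry gave 12 at t6 and 11 at t2. With no filter 19 lists were called at t2. With the baseline split into sets of 3, the correlations were 0.45 (t0 and t4), 0.36 (t0 and t6), 0.67 (t2 and t4), 0.58 (t2 and t6) and 0.65 (t4 and t6). The split removed the shared libraries and also left 3 baseline libraries for each time, and which of these lowered the values was not tested. Leaving out 1 library gave 911 (t6 349) to 2057 genes (t2 339) at t6, 571 (t6 349) to 1195 (t2 339) lasting genes, 225 (t6 341) to 492 (t2 339) late genes and 10 (baseline 355) to 17 lists (baseline 344) at t2. Spt1 turned, from −2.50 (t0 375) to 13.99 (baseline 345) at t0 and from −14.94 (t6 341) to 5.02 (t0 375) for t6 against t0. For the other changes the cause was not tested. Without the 4 doubted libraries 6939, 3196, 3481 and 1329 genes were called at t0, t2, t4 and t6, and DESeq2 called 7151, 3626, 3511 and 1790. Of 338 results of named genes (1 gene in 1 comparison, 336 of them called), DESeq2 kept 333 on their side of the threshold, limma 320 (pseudocount 1) and 327 (0.1), quantile scaling 317, quality weights 306, and 326 stayed without the 4 doubted libraries. Leaving out 1 library ended 30 of 336 gene calls and 24 of 101 list calls (1 list in 1 comparison), and moved 31 of 334 log2 values of named genes by over 1. For the 101 list calls the adjusted p with an estimated correlation was the highest of all alternatives, the others ranged from 3e-35 to 0.6, and 69 stayed under 0.05 in all others. No paired analysis was possible because the groups share no replicate numbers. The F test and trend were not run with only the groups compared. At the only depth and group sizes simulated, 13 of 67 genes changed 1.5-fold were found, so weak changes may be missed.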

Other observations

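Baseline wild-type and knockout values (CPM ± SD, n = 6 each) came from tables made separately and were not tested. The secretoglobin Scgb3a1 was at 8080 ± 2740 in wild-type and 12100 ± 4540 in knockout libraries, Cckar at 108 ± 17.4 and 174 ± 37.3, Dnah5 at 498 ± 285 and 694 ± 98.2, and Krt4 at 145 ± 75.3 and 129 ± 51.4.

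The test of sex was written before its result was seen. At t0, 0 genes had an interaction of sex and exposure (edgeR, adjusted), and 535 had one at an unadjusted p under 0.05, with no other tool run. Male and female changes correlated at 0.91 across genes called at t0, which are not independent replicates. The bound set beforehand counted few interactions as evidence against a difference, which was wrong for this design and was reconsidered after the result. With only 2 baseline males, whether the sexes differ cannot be told apart from low power.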
